A study of Oryza sativa with 6 samples.

How the data were processed

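RNA from rice seedlings harvested before lights on (AM, n = 3) or before lights off (PM, n = 3) was extracted with a Qiagen plant kit, and 2 µg of total RNA per sample went into a NEB directional library kit, per the labels' protocols. The 6 deposited files hold raw counts per gene, which the authors made with Trimmomatic 0.33, STAR and HTSeq 0.6.1, per the submitters' processing notes. The STAR version, the genome build, the annotation and the strand setting of the counting are not given in the sources used here, so no coordinates are printed, and reads of overlapping or antisense genes are then not separable. Each file lists 55801 loci under MSU identifiers, of which 24469 had no count in any library, and 5 summary lines that name no gene. These summary lines stayed out of library sizes and tests. Records aligned to more than 1 place made up 49.4% ± 5.91 of all records in AM and 44% ± 4.44 in PM (SD, n = 3). Records on no feature made up 3.53% ± 0.674 and 5.17% ± 0.982 (SD, n = 3), and ambiguous ones 0.142% ± 0.0293 and 0.147% ± 0.0145 (SD, n = 3). Only uniquely aligned reads were counted, so near-identical copies such as the Rubisco small subunit, LHCB1, nitrate reductase and EF1A genes can lose or split reads.

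Samples were grouped by the labels. Library totals of gene counts ran from 13 M to 66.7 M, and 3 counts in a library, the limit that a count of 0 allows, equal 0.0548 to 0.173 TMM-normalised CPM. Counts of replicates differed by more than sampling noise in every pair (chi-square per degree of freedom 20.4 to 148), so all 6 libraries were kept as separate samples.

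PM was compared with AM by the edgeR 4.0.16 quasi-likelihood test (glmQLFit and glmQLFTest, R 4.3.3) with TMM factors, filterByExpr (minimum count 10), which left 20548 loci, and Benjamini-Hochberg adjustment at 0.05. Fold changes are PM over AM on the log2 scale, and SEs come from the fitted coefficient and its F statistic. CPM values are TMM-normalised and were computed from the counts. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, both directions), adjusted over the 20 lists with at least 3 tested members. Of the 10 lists past the threshold, 0 were past it with an estimated correlation. With fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, 13 lists passed. Adjusted over the list alone, 17 of the 21 lists had the same counts of higher and lower members, and the other 4 are given with their lists. Of the 150 called list members, 146 had no overlap between AM and PM values; the exceptions were CHLM, HSP101, HSP16.9A and HKT2;1.

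The 21 lists, the rule for named genes, the tests and most other settings were fixed before the data were examined. The rule names every tested clock and flowering gene. From each other list it names up to 4 genes, namely the 2 called members with the smallest p in each direction, or failing that the member with the smallest p. It also names the 10 largest rises and 10 largest falls among called loci with a mean log2 CPM of at least 3 and no overlap, where a name is known, and otherwise at most 2 identifiers per direction. Floral and root markers with no or single counts and AKT1 were named after their values were seen. List members were placed by MSU identifiers. Of 229 entries, 3 were not among the loci of the files. Names were compared with the RefSeq gene table of assembly ASM3414082v1, which holds no MSU identifiers, by symbol, chromosome and gene order. This matched 122 entries and dropped 6, namely PSAG, SPS1, HSP90 and UBQ5, on another chromosome, and GLO4 and GLB, in reversed order. The other 98 of the 220 entries kept rest on the lists alone. Alternate symbols for 15 entries were added after the values had been seen.

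The edgeR test and the camera test with the preset correlation were tried on simulated counts for the 20548 loci with the means and library sizes of these samples. Both groups had the same mean at all unchanged loci. The single changed loci lay above 5 CPM, with as many raised as lowered. TMM scaling under a shift as broad as the one found here was therefore not tested, and the rates below need not hold for it. Counts were drawn independently for each locus, so list members had no correlation with one another. Whether such correlation leads to false list calls was therefore not tested. The estimated correlation and fry were not tried in this way. For PM against AM, 36% of 100 loci changed 2-fold and 98% of 100 loci changed 4-fold were recovered, 11 unchanged loci were called, a changed list was called and 0 of 20 unchanged lists were. Other settings fixed in the same way were RLE and upper-quartile scaling, no filter, a mean of at least 5 CPM, a replicate block, glmTreat against a 2-fold change, a threshold of 0.01, DESeq2 1.42.0, limma-voom, estimated correlation, fry and leaving out each library. Scaling by library totals only, thinning all libraries to the smallest and list counts without each library were added after seeing the data. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3. The values of 1 gene that the rule names are not reported here. Alternative splicing and mappings to other genomes were not analysed here.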

Results

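Rice (Oryza sativa) plants of the cultivar Nipponbare were sampled at the end of the night and at the end of the day, and their RNA was sequenced with a kit that keeps strand information. Plants grew on Chu's medium at 28 °C with 12 h of light and 12 h of darkness. The 3 AM libraries came from plants taken 30 min before the lights came on, and the 3 PM libraries from plants taken 30 min before the lights went off. The labels describe whole frozen seedlings as the starting material, yet they also give the organ as panicle; levels of floral genes are given with the tissue markers. Gene counts came to 22.3 M, 66.7 M and 36.1 M in AM replicates 1, 2 and 3, and to 20.4 M, 13 M and 41.7 M in PM replicates 1, 2 and 3. Nothing in the labels states that the replicates were separate plants or cultures, so p-values measure only the spread between these samples, which may be technical. The series was set up to compare gene expression and splicing between the time points and to ask how the reference genome alters such results; splicing and mappings to other genomes were not analysed here.

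The end-of-day and end-of-night transcriptomes differed at a large share of the expressed loci. Of 20548 loci tested, 5748 were higher and 5745 lower in PM with the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, which is 55.9% of the loci. Changes over 4-fold numbered 1908 higher and 2198 lower, of which 91 and 90 rested on a group with 3 or fewer counts (87 to 207 and 72 to 264 with any 1 library left out). The AM and PM values did not overlap at 64.1% of the loci, against 10% by chance for 3 samples against 3. Spearman correlations of log2 CPM across loci lay between 0.965 and 0.988 for libraries of 1 group and between 0.759 and 0.813 for libraries of different groups, and loci are not independent replicates. The first principal component held 84.7% of the variance. In AM, 27.1% ± 3.92 (SD, n = 3) of all gene counts fell on the antenna, photosystem and Calvin cycle lists, against 5.46% ± 0.822 (SD, n = 3) in PM. Fold changes depend on the scaling: by library totals alone the median locus lay 0.84 log2 units higher in PM, and after TMM scaling it lay at −0.01. With library totals alone, 80.2% of the calls were higher in PM (11201 higher, 2764 lower), against 50% after TMM scaling, and 3825 and 1223 of them exceeded 4-fold. All changes below are therefore relative to the median locus.

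Most clock genes differed between the 2 times of day. Of the 13 genes in the list, 6 were higher and 5 lower in PM, and the values of these 11 did not overlap between the groups. LHY (LOC_Os08g06110), a MYB transcription factor that peaks around dawn, was at 3979 ± 175 CPM in AM and 5.06 ± 2.55 in PM (CPM are TMM-normalised; mean ± SD, n = 3 here and below). Its log2 fold change of PM over AM was −9.65 (SE 0.50), with an edgeR quasi-likelihood adjusted p of 2.34e-06. Among the pseudo-response regulators, which repress transcription in sequence through the day, PRR73 (LOC_Os03g17570; log2 −4.22, SE 0.20) and PRR95 (LOC_Os09g36220; −4.17, SE 0.24) were lower in PM. PRR1 (LOC_Os02g40510; 1.90, SE 0.26) and PRR59 (LOC_Os11g05930; 1.64, SE 0.21) were higher. PRR37 (LOC_Os07g49460) was lower by a small amount (−0.82, SE 0.25, edgeR adjusted p = 0.0224), a call that ended without PM replicate 1 (−0.70, adjusted p = 0.0922) and with library totals alone (−0.01). LUX (LOC_Os01g74020) and ELF3-2 (LOC_Os01g38530), relatives of the Arabidopsis evening complex proteins, rose from 0.525 ± 0.348 to 134 ± 57.5 CPM and from 11.5 ± 4.14 to 162 ± 0.906 CPM. These are log2 changes of 8.17 (SE 0.52) and 3.82 (SE 0.28). The blue-light receptor FKF1 (LOC_Os11g34460) rose by 6.60 (SE 0.46), or by 7.30 without AM replicate 2, and GI (LOC_Os01g08700) rose by 1.69 (SE 0.30). ZTL1 (LOC_Os02g05700) was lower after TMM scaling (−0.61, SE 0.15) and at 0.24 with library totals alone. ELF3-1 (LOC_Os06g05060) was at −0.22 (SE 0.16) and ZTL2 (LOC_Os06g47890) at −0.23 (SE 0.16), neither past the threshold, and both passed it in the other direction with library totals alone, at 0.63 and 0.62. With that scaling 8 clock genes were higher and 3 lower. The list as a whole had no common direction (limma camera, adjusted p = 0.971); its median was −0.22, its mean 0.30 and the test pointed down.

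**Figure D1:**
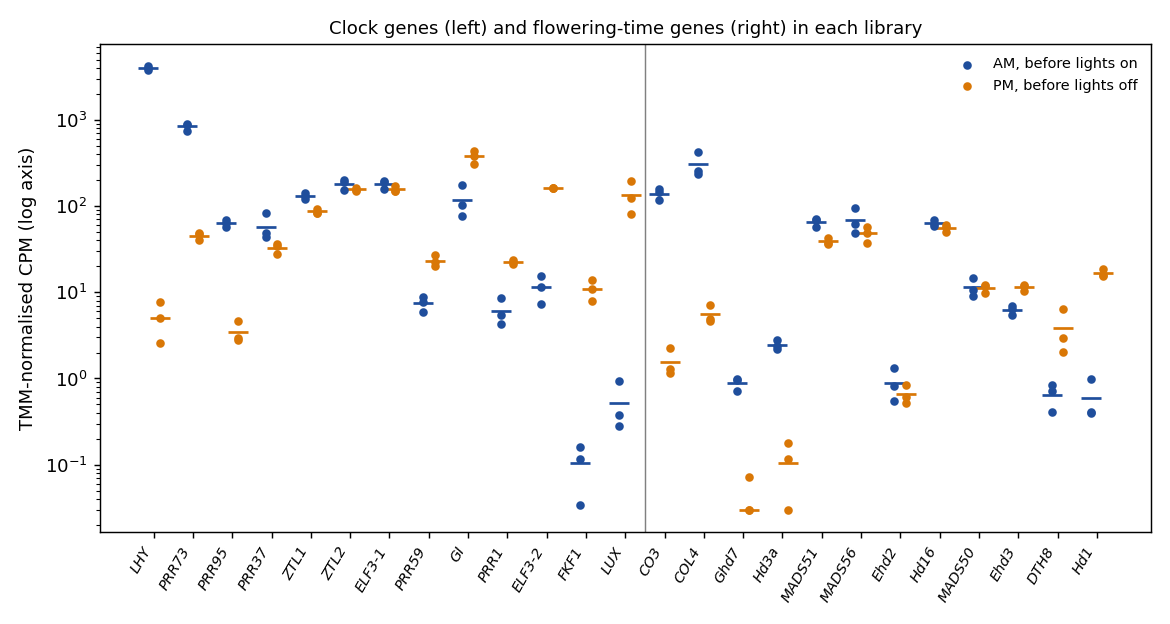
TMM-normalised CPM (log axis) of the tested clock genes (left of the line) and flowering-time genes (right of it), with 1 point per library, AM in blue and PM in orange, and a bar at each group mean; 3 values under 0.03 CPM are drawn at 0.03. LHY falls from 3979 ± 175 to 5.06 ± 2.55 CPM (mean ± SD, n = 3) and LUX rises from 0.525 ± 0.348 to 134 ± 57.5 CPM.

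Of the 12 flowering-time genes tested, 3 were higher and 5 lower in PM. Hd1 (LOC_Os06g16370), the rice counterpart of CONSTANS, rose from 0.594 ± 0.335 to 16.5 ± 1.62 CPM, a log2 change of 4.91 (SE 0.36, edgeR adjusted p = 1.21e-05). DTH8 (LOC_Os08g07740), a NF-Y subunit that represses flowering in long days, rose by 2.52 (SE 0.51), or by 1.90 without PM replicate 3. Ehd3 (LOC_Os08g01420), which promotes flowering, rose by 0.87 (SE 0.19). The CONSTANS-like genes CO3 (LOC_Os09g06464) and COL4 (LOC_Os02g39710) were far lower in PM, at log2 −6.42 (SE 0.30) and −5.76 (SE 0.33). Transcripts of the florigen gene Hd3a (LOC_Os06g06320) were few, with 230 counts in the AM libraries together and 8 in the PM libraries. Its log2 change was −4.75 (SE 0.63), ranging to −5.61 without PM replicate 1 and −3.99 without PM replicate 3. The floral repressor Ghd7 (LOC_Os07g15770) had 79 counts in AM and 2 in PM, a 44-fold ratio of AM over PM with a 95% exact counting interval of 11.8 to 369, and its edgeR adjusted p was 0.00182 without PM replicate 1 and 0.00439 without PM replicate 3. MADS51 (LOC_Os01g69850) was lower by the TMM scale (−0.75, SE 0.15) and at 0.10 with library totals alone. The other 4 did not pass the threshold and all changed sign with library totals alone: Ehd2 (LOC_Os10g28330) from −0.39 (SE 0.46) to 0.46, MADS56 (LOC_Os10g39130) from −0.51 (SE 0.26) to 0.32, Hd16 (LOC_Os03g57940) from −0.19 (SE 0.15) to 0.65 and MADS50 (LOC_Os03g03070) from −0.03 (SE 0.22) to 0.81. Of these, Hd16 and MADS50 then passed the threshold. MADS50 also stood at 0.19 without AM replicate 3 and 0.07 without PM replicate 2. The list median of −0.45, the same with Ghd7 at its lower bound, moved to 0.39 with library totals alone, where 5 genes were higher and 4 lower, and limma camera gave an adjusted p of 0.122.

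Light receptors and their partners changed in both directions. All 3 phytochrome genes were higher in PM, with PHYC (LOC_Os03g54084) rising from 35.4 ± 1.37 to 113 ± 5.04 CPM (log2 1.68, SE 0.14) and PHYB (LOC_Os03g19590) by 1.46 (SE 0.15). The other 7 called members were lower in PM, among them the phytochrome-interacting factor-like genes PIL13 (LOC_Os03g56950), at −5.99 (SE 0.29), and PIL11 (LOC_Os12g41650), at −4.05 (SE 0.19). Adjusted over the list alone, 3 of the 12 tested were higher and 8 lower. With library totals alone 4 were higher and 4 lower. The list as a whole was lower in PM (median −1; limma camera, adjusted p = 0.0228), with adjusted p = 0.233 with an estimated correlation.

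Nuclear genes for the light-harvesting antenna had the lowest median fold change of the 21 lists. All 13 antenna genes and all 12 photosystem subunit genes were lower in PM, with no overlap between the groups and with medians of −10.04 and −4.32. Antenna genes took 9.13% ± 1.98 (SD, n = 3) of the gene counts in AM and 0.0363% ± 0.00698 (SD, n = 3) in PM. LHCB4 (LOC_Os07g37240), a minor antenna protein of photosystem II, fell from 12459 ± 4246 to 35.6 ± 0.292 CPM, a log2 change of −8.45 (SE 0.39, edgeR adjusted p = 1.56e-06). LHCB6 (LOC_Os04g38410) was at −10.04 (SE 0.56). Of the photosystem I subunits, PSAO (LOC_Os04g33830) was at −8.86 (SE 0.43) and PSAK (LOC_Os07g05480) at −5.99 (SE 0.38). Among the 10 largest falls of all loci were LHCB1a (LOC_Os01g41710), LHCA4 (LOC_Os08g33820) and LHCB1b (LOC_Os09g17740), at −10.80 (SE 1.08), −10.72 (SE 0.85) and −10.60 (SE 0.94). PM replicate 2 held more of these transcripts than the other PM libraries, and without it the 3 values were −12.16, −11.70 and −11.80 and the antenna median −10.60. In AM replicate 3, antenna genes lay below both other AM libraries at 8 of 13 members, with a median log2 ratio of −0.50, and photosystem genes at 7 of 12 (−0.46). AM replicate 2 was the highest, and as the ratios are against the mean of AM replicates 1 and 2, its level adds to them. At any locus 1 of the 3 AM libraries is the lowest and another the highest. Such counts were not made over all loci or for AM replicates 1 and 2, so those given here and for the lists below have no baseline. Antenna genes took 8.165%, 11.41% and 7.812% of raw gene counts in AM replicates 1, 2 and 3. Photosystem genes took 4.69%, 6.556% and 4.866%. LHCB1 copies resemble one another, so the split of reads between them is uncertain. Both lists passed the set test (limma camera, adjusted p = 1.29e-16 and 3.02e-14), each with adjusted p = 0.233 with an estimated correlation.

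Calvin cycle genes were lower in PM as well, though by less. Of 14 tested, 13 were lower and 1 did not pass, with a median of −1.70. Adjusted over the list alone, all 14 were lower. With library totals alone 10 were lower and 0 higher, with a median of −0.84. At 7 of the 14, AM replicate 3 lay below both other AM libraries (median log2 ratio −0.21). By share of raw gene counts AM replicate 2 was again the highest, at 13.66% against 11.97% and 12.18% in AM replicates 1 and 3. RCA (LOC_Os11g47970), which encodes Rubisco activase, fell from 34877 ± 8239 to 1573 ± 397 CPM (log2 −4.47, SE 0.36), and PRK (LOC_Os02g47020), for phosphoribulokinase, from 8572 ± 836 to 1157 ± 27.3 CPM (−2.89, SE 0.23). The limma camera adjusted p was 2.33e-07, with adjusted p = 0.234 with an estimated correlation. Of 12 genes for photorespiration and catalases, 6 were lower and 6 did not pass. GDCP (LOC_Os01g51410), a subunit of glycine decarboxylase, was at −3.98 (SE 0.23), and PGLP (LOC_Os04g41340), for phosphoglycolate phosphatase, at −2.77 (SE 0.19). This list had a median of −0.75 and a limma camera adjusted p of 0.0114, with adjusted p = 0.234 with an estimated correlation. With library totals alone its median was 0.09, with 5 members higher and 5 lower, and 1 was higher without AM replicate 2.

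Chlorophyll and carotenoid synthesis moved in the same direction as the antenna, with a few exceptions in each pathway. Of 12 tetrapyrrole genes, 10 were lower and 2 higher in PM, against 8 lower and 2 higher with library totals alone. CRD1 (LOC_Os01g17170), a cyclase subunit of chlorophyll synthesis, fell from 3529 ± 782 to 27.6 ± 0.466 CPM (log2 −7.00, SE 0.29, edgeR adjusted p = 1.11e-06), and CAO1 (LOC_Os10g41780), which makes chlorophyll b, was at −6.07 (SE 0.24). The 2 that rose were CHLG (LOC_Os05g28200), for chlorophyll synthase, at 2.56 (SE 0.24), and CHLD (LOC_Os03g59640), a magnesium chelatase subunit, at 1.19 (SE 0.17). Of 11 carotenoid genes, 7 were lower and 2 higher, against 6 lower and 4 higher with library totals alone. BCH2 (LOC_Os04g48880), a carotene hydroxylase, was at −8.34 (SE 0.34), or −8.99 without PM replicate 3. ZEP (LOC_Os04g37619), for zeaxanthin epoxidase, was at −6.55 (SE 0.28), while VDE (LOC_Os04g31040), for the violaxanthin de-epoxidase that works in the reverse sense, rose from 152 ± 8.11 to 258 ± 13.7 CPM (0.76, SE 0.15). LCYB (LOC_Os02g09750), for lycopene beta-cyclase, rose by 0.76 (SE 0.27, edgeR adjusted p = 0.0411). That call ended without AM replicate 1 (0.53), AM replicate 2 (0.79), PM replicate 1 (0.79) or PM replicate 3 (0.59), leaving 1 higher member in each case. The limma camera adjusted p was 1.46e-08 for tetrapyrrole and 8.57e-06 for carotenoid synthesis, each with adjusted p = 0.0943 with an estimated correlation.

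Starch genes went both ways. Of 11 starch synthesis genes tested, 7 were lower, 1 was higher and 3 did not pass; adjusted over the list alone, 8 were lower, and with library totals alone 3 were higher and 6 lower. AM replicate 3 lay above both other AM libraries at 7 of the 11 (median log2 ratio 0.16). GBSSII (LOC_Os07g22930), the granule-bound starch synthase of leaves, fell from 676 ± 208 to 1.24 ± 0.498 CPM (log2 −9.17, SE 0.42, edgeR adjusted p = 1.52e-06), and AGPL3 (LOC_Os05g50380), an ADP-glucose pyrophosphorylase subunit, was at −2.88 (SE 0.24). ISA1 (LOC_Os08g40930), a debranching isoamylase that trims amylopectin, was the one that rose, from 1.35 ± 0.0964 to 65.4 ± 7.55 CPM (5.59, SE 0.20). The limma camera adjusted p was 0.025, with adjusted p = 0.467 with an estimated correlation, and 0.0625 without PM replicate 3, where 2 members were higher. Of 9 starch breakdown genes, 3 were higher and 4 lower, against 5 higher and 2 lower with library totals alone. AM replicate 3 lay below both other AM libraries at 5 of the 9 (median log2 ratio −0.45), with BAM2 at 379 CPM there and 916 and 1164 in AM replicates 1 and 2. The beta-amylase genes parted, with BAM3 (LOC_Os10g41550) rising by 3.81 (SE 0.25) and BAM2 (LOC_Os03g04770) and BAM1 (LOC_Os10g32810) at −4.20 (SE 0.43) and −3.58 (SE 0.30). DPE2 (LOC_Os07g46790), a disproportionating enzyme acting on maltose, rose from 274 ± 86.6 to 547 ± 101 CPM. Without PM replicate 1, 2 members were higher. This list's median was 0.06, its mean −0.17 and its camera direction down (limma, adjusted p = 0.971).

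The 5 sucrose genes tested held 2 higher and 2 lower, against 3 higher and 0 lower with library totals alone. AM replicate 3 lay above both other AM libraries at 4 of the 5, with a median log2 ratio of 0.46. The sucrose synthase gene SUS1 (LOC_Os03g28330) rose from 2.69 ± 3.18 to 21.3 ± 5.54 CPM (log2 2.96, SE 0.71), or by 4.57 without AM replicate 3. SUS2 (LOC_Os06g09450) rose by 0.66 (SE 0.19, edgeR adjusted p = 0.0164), with no call without AM replicate 1 (0.63), AM replicate 2 (0.61) or PM replicate 1 (0.58). The sucrose transporter genes SUT2 (LOC_Os12g44380) and SUT1 (LOC_Os03g07480) were at −1.18 (SE 0.19) and −1.08 (SE 0.41, edgeR adjusted p = 0.0494). Neither was called with library totals alone (−0.35 and −0.28), and the SUT1 call also ended without AM replicate 3 (−0.41), PM replicate 1 (−1.17), PM replicate 2 (−0.87) or PM replicate 3 (−1.20). The median was −0.12, the mean 0.25 and the test pointed down (limma camera, adjusted p = 0.971).

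Nitrogen assimilation was mostly lower in PM, with 8 of 11 tested genes lower and 1 higher (7 and 2 with library totals alone). The nitrate reductase genes NIA1 (LOC_Os08g36480) and NR2 (LOC_Os02g53130) were at log2 −6.42 (SE 0.40) and −10.73 (SE 1.07), the latter at −10.01 without PM replicate 3. The ammonium transporter gene AMT1;1 (LOC_Os04g43070) fell from 483 ± 81.6 to 10.03 ± 2.37 CPM (−5.58, SE 0.26). ASN1 (LOC_Os03g18130), for an asparagine synthetase, rose from 60.6 ± 7.84 to 489 ± 56.1 CPM (3.01, SE 0.19, edgeR adjusted p = 5.85e-06). The list had a median of −1.74 and a limma camera adjusted p of 0.00217, with adjusted p = 0.234 with an estimated correlation. In AM replicate 3, 8 of the 11 lay below both other AM libraries, with a median log2 ratio of −0.43.

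Of 6 phenylpropanoid entry genes tested, 5 were lower in PM and none higher, with a median of −2.68. Several of the ammonia-lyase genes are close copies that can share reads. C4H (LOC_Os05g25640), for cinnamate 4-hydroxylase, was at −2.72 (SE 0.25) and PAL6 (LOC_Os04g43760), for a phenylalanine ammonia-lyase, at −1.93 (SE 0.21). The limma camera adjusted p was 0.0172, with adjusted p = 0.467 with an estimated correlation and 0.0537 when only loci with a mean of at least 5 CPM were kept. AM replicate 3 lay above both other AM libraries at 5 of the 6, with a median log2 ratio of 0.89.

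Heat shock genes varied widely within AM. Of 7 tested, 4 were lower and 1 higher in PM, and all 7 were lower in AM replicate 3 than in both other AM libraries, with a median log2 ratio of −2.65. HSFA2d (LOC_Os03g06630), a class A2 heat shock factor, fell from 78.8 ± 20.1 to 1.57 ± 0.752 CPM (log2 −5.57, SE 0.37), and its relative HSFA2c (LOC_Os10g28340) rose by 1.24 (SE 0.33). The small heat shock protein gene HSP18.0 (LOC_Os03g16030) was at −4.89 (SE 0.97), and between −4.24 without AM replicate 2, −4.27 without PM replicate 3 and −5.57 without PM replicate 2. Without AM replicate 3, 7 of 8 tested were lower and the limma camera adjusted p went from 0.13 to 0.0102, and without PM replicate 3, 6 of 8 were lower. The camera p was also past the threshold with library totals alone (0.029), with no filter on low counts (0.0433) and with the replicate block (0.00882). With limma-voom, 2 of the 7 were lower.

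Of 6 cold and drought response genes tested, 3 were lower and none higher; adjusted over the list alone, 1 was higher and 3 lower. At 4 of the 6, AM replicate 3 lay above both other AM libraries (median log2 ratio 0.39). LIP9 (LOC_Os02g44870), a dehydrin gene, was at −3.45 (SE 0.27) and SALT (LOC_Os01g24710) at −3.92 (SE 0.44). The limma camera adjusted p was 0.0816, and it passed the threshold without AM replicate 1 (0.0453) and with library totals alone (0.0319). Without AM replicate 3, or with library totals alone, 1 member was higher. Of 5 cell division genes, 2 were higher and 3 lower, against 2 and 0 with library totals alone. PCNA (LOC_Os02g56130), the sliding clamp of DNA replication, rose by 1.97 (SE 0.25), and CDKB1;1 (LOC_Os01g67160) by 0.58 (SE 0.21, edgeR adjusted p = 0.0383). The mitotic genes CYCB1;1 (LOC_Os01g59120) and CDKB2;1 (LOC_Os08g40170) were at −1.93 (SE 0.51) and −2.22 (SE 0.60), at 1.37 ± 0.727 and 1.05 ± 0.641 CPM in AM, and neither was called with library totals alone (−1.12 and −1.40). AM replicate 3 lay above both other AM libraries at all 3 lower members and below both at the 2 higher ones, with CYCB1;1 at 2.21 CPM there and 0.923 and 0.971 in AM replicates 1 and 2. The CDKB1;1 call ended without AM replicate 2 (0.58), AM replicate 3 (0.49), PM replicate 1 (0.67), PM replicate 2 (0.60) or PM replicate 3 (0.50), leaving 1 higher member. Lower members numbered 1 of 3 tested without AM replicate 2 or AM replicate 3, 2 of 6 without PM replicate 1 and 2 of 5 without PM replicate 3. The median was −1.93 while the test pointed up (limma camera, adjusted p = 0.971). That median turned to 0.58 without AM replicate 2 and 0.49 without AM replicate 3, each with 3 genes tested. With 2 genes tested, it was 1.25 at a mean of at least 5 CPM and 1.26 after thinning to the smallest library.

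**Figure D2:**
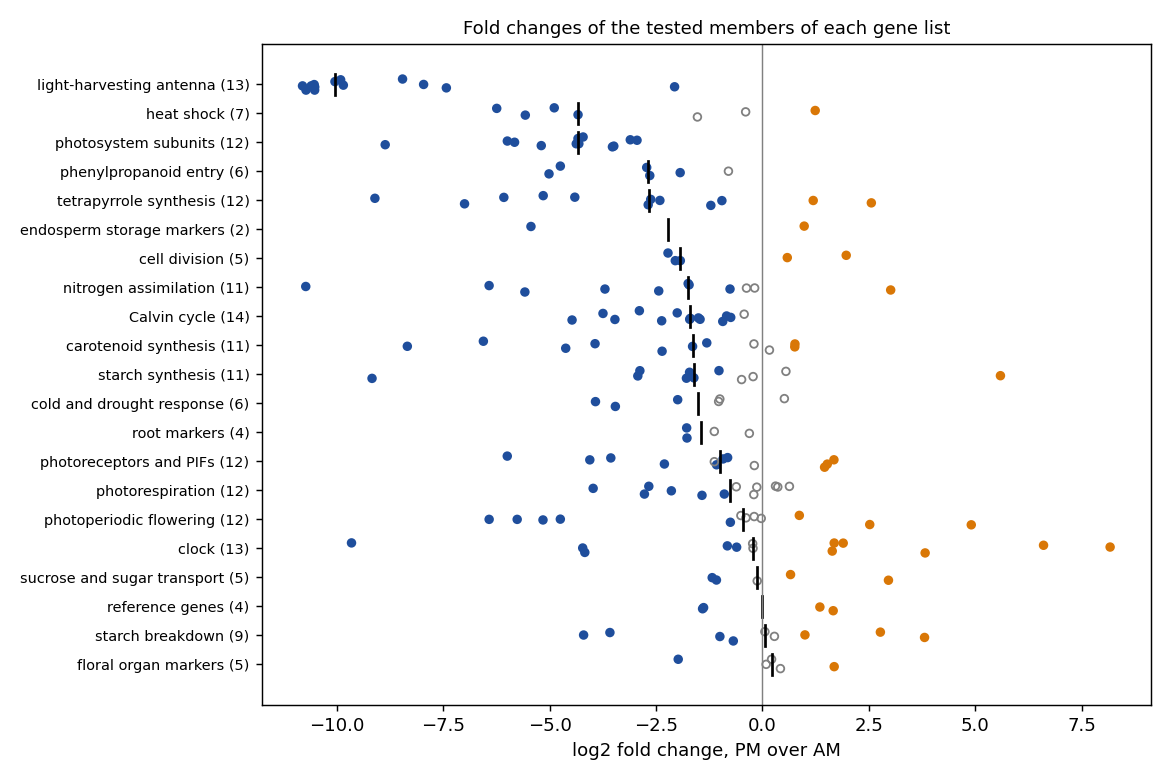
Log2 fold changes of PM over AM for the tested members of the 21 lists, with their number in brackets; each point is 1 gene, orange and blue where it was higher or lower in PM by the edgeR test, open grey where it did not pass, and the black bar is the list median. The antenna list has the lowest median, −10.04, and in the fit drawn the floral markers have the highest, 0.22. Without PM replicate 2 the floral median was −0.02, below that of the sucrose list (0.15). Scaled by library totals alone, all medians shift up. Those of the clock (0.63), flowering (0.39), photorespiration (0.09), sucrose (0.74) and reference gene (0.83) lists then turn positive.

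No floral organ gene exceeded 5.33 CPM in either group mean. Of 13 floral organ genes, 3 had no counts in the 6 libraries (MADS8, MADS13 and FZP), and MADS6 and MADS7 had 1 count each. The highest, MADS16 (LOC_Os06g49840), a stamen and lodicule identity gene, was at 5.33 ± 1.01 CPM in AM and 1.30 ± 0.736 in PM (log2 −1.98, SE 0.42), and MADS58 (LOC_Os05g11414) was at 0.458 ± 0.151 and 1.51 ± 0.336 CPM (1.69, SE 0.41). The other 3 tested members did not pass; with library totals alone the list had 2 higher and 1 lower, and the set test gave a limma camera adjusted p of 0.971. Of 8 root markers, 2 had no counts and 4 were tested, of which 2 were lower (1 with library totals alone). The potassium channel gene AKT1 (LOC_Os01g45990) was at 11.9 ± 3.64 CPM in AM and 9.62 ± 1.57 in PM and did not pass. The silicon channel gene LSI1 (LOC_Os02g51110) was at 22.1 ± 6.13 CPM in AM and 6.44 ± 0.563 in PM (−1.78, SE 0.24), and the sodium transporter gene HKT2;1 (LOC_Os06g48810) at −1.77 (SE 0.63, edgeR adjusted p = 0.0395). The HKT2;1 call ended without AM replicate 3 (−0.72), PM replicate 2 (−1.54) or PM replicate 3 (−1.63) and with library totals alone (−0.98). Without AM replicate 1, 3 of 5 root markers tested were lower. The root list gave a limma camera adjusted p of 0.372. Of 6 seed storage markers, 2 were tested. GBSSI (LOC_Os06g04200), the Waxy starch synthase, was at 6.70 ± 0.986 CPM in AM and 0.134 ± 0.0721 in PM (−5.44, SE 0.39). GLUA2 (LOC_Os10g26060), a glutelin gene, rose from 2.04 ± 0.436 to 4.02 ± 0.822 CPM (0.98, SE 0.29), a call that ended without AM replicate 2 (0.92), PM replicate 1 (1.04) or PM replicate 2 (0.82).

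Genes commonly used to normalise PCR assays changed too, and all 4 tested kept their direction with library totals alone. ACT1 (LOC_Os03g50885), for an actin, was at log2 −1.41 (SE 0.15). The elongation factor genes EF1A2 (LOC_Os03g08020) and EF1A1 (LOC_Os03g08010), neighbouring copies that can share reads, rose by 1.66 (SE 0.19) and 1.35 (SE 0.21). The list had a median of −0.02, a mean of 0.06 and a test that pointed down (limma camera, adjusted p = 0.971).

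The files pair no locus with a name, and most of the 10 largest rises and 10 largest falls were loci outside the 21 lists. LOC_Os01g65130 had 1 count in AM, in AM replicate 1, and 1757 in PM, a ratio of 1580 with a 95% exact counting interval of 283 to 62400. LOC_Os04g57880 rose from 0.524 ± 0.253 to 267 ± 27.3 CPM (log2 9.11, SE 0.33, edgeR adjusted p = 9.54e-07). In the other direction, LOC_Os02g04550 had 1618 counts in AM and none in PM, which is at least 600-fold lower when set against 3 counts over the PM group. LOC_Os03g18060 had 1847 counts in AM and none in PM, and its AM values were uneven, at 51.7 CPM in AM replicate 3 and 5.89 and 5.16 CPM in AM replicates 1 and 2. Intervals and floors cover counting error only.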

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

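The tests of depth and of harvest state for PM replicate 2 and the symmetric check of the other PM libraries were chosen after the result was seen. In AM replicate 2, 56.14% of all records were aligned to more than 1 place and so lay outside the gene counts; this is a signal in data that the comparisons did not use. HTSeq can list a read once for each of its alignments, so the value is a share of records and not of reads.

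With CPM by library totals, at 13 loci above 500 CPM in AM and under 0.2% of that level in the mean of PM replicates 1 and 3, PM replicate 2 exceeded both of those libraries, by a median of 0.181% of the AM level; 9 were antenna genes, and at other AM-high genes, such as RCA and PSAK, it was the lowest PM library. At 1213 loci 4-fold to 64-fold higher in AM, PM replicate 2 had a median log2 ratio of −0.301 to the other PM libraries, so these loci did not move towards AM as a set. This test cannot decide on a shift of the plants as small as the excess, which would raise such loci only a little. Nor can it decide on a shift limited to the antenna genes. Lower depth, which adds counting error alone, is argued against by the antenna list, not chosen on PM levels: the exact 95% counting interval of PM replicate 2 lay wholly above those of both other PM libraries at 9 of 13 members and wholly below both at 1. A candidate explanation is a small carry-over of AM reads or RNA: at 10 loci chosen likewise at 50 to 500 CPM in AM the median excess was 0.185% (95% bootstrap interval 0.104 to 0.281), where a carry-over set by the abundant loci predicted 0.1 to 0.3. These 10 loci held only 63 counts in PM replicate 2 together, and the interval covers the spread between loci but not counting error. LHCB4 and CRD1, also high in AM, were not among the loci chosen. Their PM values lay close together, at 35.6 ± 0.292 and 27.6 ± 0.466 TMM-normalised CPM (SD, n = 3), so PM replicate 2 showed no excess there. A carry-over should reach such genes too, and whether a lower level in PM replicate 2 hid it was not tested. With loci chosen the same way for each, PM replicates 1 and 3 gave −0.068% (8 loci) and −0.128% (7 loci) in the higher set. In the lower set they gave 0.0199% (−0.0261 to 0.172, 4 loci) and −0.0844% (−0.15 to 0.0887, 3 loci), and the interval of PM replicate 1 overlaps that of PM replicate 2 there. PM replicate 2 was part of the mean that each was set against, so its excess alone pushes these values down. They are therefore no independent check.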

How the results depend on the processing

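Scaling by library totals only and thinning to the smallest library were chosen after the result was seen; the rest was planned. Counts of higher and lower loci stayed within 1.5 times of 5748 and 5745 under RLE and upper-quartile scaling, both filters, the block, DESeq2, limma-voom, the 0.01 threshold and thinning. They were 2663 and 2834 with glmTreat, which asks for more than a 2-fold change, and 11201 and 2764 with library totals only. Leaving out 1 library gave 4847 to 6061 higher and 4821 to 5800 lower. Of 99 named genes, RLE scaling kept the call and direction of all 99 and DESeq2 of all 98 it tested. Calls ended, with the direction kept, at 19 genes with glmTreat, 10 at the 0.01 threshold, 6 without PM replicate 1 and 6 with library totals. Each other setting ended 1 to 4 calls in this way. Library totals turned 8, to log2 0.63 for ELF3-1, 0.24 for ZTL1, 0.62 for ZTL2, 0.46 for Ehd2, 0.81 for MADS50, 0.10 for MADS51, 0.32 for MADS56 and 0.65 for Hd16. MADS50, at −0.03 in the fit reported, was also above 0 with no filter (0.00597), limma-voom (0.0003003), thinning (0.0146) and without AM replicate 3 (0.19) or PM replicate 2 (0.07), with a lowest value of −0.15 without AM replicate 1. Depth limits loci near the floor of 0.0548 to 0.173 TMM-normalised CPM. Where a result turned or crossed the threshold, the cause was not tested.

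In limma camera, adjusted p with an estimated correlation was 0.233 for photoreceptors, antenna and photosystems, 0.234 for the Calvin cycle, photorespiration and nitrogen, 0.0943 for tetrapyrroles and carotenoids, and 0.467 for starch synthesis and phenylpropanoids. With fry (limma), adjusted p passed for flowering (0.000316), cold and drought (0.00209) and root markers (0.00533). Library totals gave limma camera adjusted p of 0.029 for heat shock and 0.0319 for cold and drought. The direction turned, without passing, for the clock (0.962), sucrose (0.998), cell division (0.962), floral markers (0.879) and reference genes (0.879). With no filter, heat shock passed (camera 0.0433), and cell division (0.973) and floral markers (0.973) turned. Phenylpropanoids did not pass at a mean of 5 CPM (0.0537). RLE scaling turned the clock (0.982).

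The values gave no sign that replicate numbers pair the samples: same-numbered deviations correlated at −0.0579, −0.273 and 0.102, and not every sample correlated best with its own number. Deviations cancel out within each group, and the correlations were not tested, so pairing is not excluded. The replicate block gave 5077 higher and 5060 lower loci, limma camera adjusted p of 0.00882 for heat shock, and turned directions for the clock (0.955), sucrose (0.986), cell division (0.986) and reference genes (0.986).

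Leaving out each library moved the limma camera adjusted p over these ranges. Lists past the threshold throughout were photoreceptors (0.0103 to 0.0451), antenna (5.62e-32 to 1.62e-14), photosystems (1.17e-20 to 1.33e-12), the Calvin cycle (4.23e-08 to 2.41e-06), photorespiration (0.00599 to 0.0246), tetrapyrroles (1.36e-10 to 1.39e-07), carotenoids (3.65e-06 to 4.02e-05), nitrogen (7.37e-06 to 0.00361) and phenylpropanoids (0.0027 to 0.0352). Starch synthesis (0.0103 to 0.0625), heat shock (0.0102 to 0.201) and cold and drought (0.0453 to 0.112) crossed it. The others stayed above it: clock (0.898 to 0.993), flowering (0.0676 to 0.159), starch breakdown (0.615 to 0.993), sucrose (0.615 to 0.993), cell division (0.476 to 0.993), floral markers (0.906 to 0.999), root markers (0.241 to 0.412) and reference genes (0.906 to 0.999).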

Other observations

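The tests in this part were set before their results were seen, except the scaling by library totals only, which was chosen after the result was seen. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called as many loci: 11493 with the edgeR quasi-likelihood test, against 0 in the highest other split. At an unadjusted p under 0.05, edgeR gave 12523 loci in the real split and 19 to 506 in the others. With 10 splits the share cannot fall under 0.05. Each other split also put AM and PM libraries into both groups, so their difference counted as spread within groups and few calls were bound to follow. The splits therefore cannot decide how many calls would arise by chance.

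The share of higher calls moved from 50% with TMM to 80.2% with library totals only, where the median locus lay at 0.84. A few abundant loci taking many of the AM counts may account for part of this: the 100 most abundant loci held 44% ± 4.62 of gene counts in AM and 21.8% ± 1.5 in PM (SD, n = 3), and with the 100 most abundant AM loci left out of the totals the median was 0.229. Choosing the loci on AM levels alone tends to lower this median whatever the cause. The most abundant PM loci were not left out in turn, so the size of that part is uncertain. The part that remains stays open, and whether the amount of RNA per plant differed between the times was not tested.

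Neighbouring loci tended to change the same way. Among 3785 pairs of called direct neighbours, 59.6% had the same direction, where 1000 permutations reached at most 52.7%. Reads spilling onto a direct neighbour might add to this, but as the whole cause they are argued against by pairs 3 tested loci apart. Of these, 53.3% shared a direction against at most 52.6% in permutations (permutation p = 0.001, the smallest these can give). At 20 tested loci the share was 49.9%, and at 50 tested loci 51.5% (permutation p = 0.012). These distances skip untested loci, while direct neighbours were adjacent among all loci of the files. Duplicated genes and shared regulation of neighbours stay open, untested.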
